A study of Mus musculus with 18 samples.

How the data were processed

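Binding of 3 mouse bZIP (basic leucine zipper) transcription factors to DNA with modified cytosine was measured on protein binding microarrays, in which a tagged protein binds double-stranded DNA probes on an array and is read by fluorescence. The proteins were the DNA-binding domains of CREB1, ATF1 and JUND, fused to glutathione S-transferase and made by in vitro transcription and translation, per the labels' protocols. Per the same protocols, the probes were made double-stranded by primer extension with cytosine (C), 5-methylcytosine (5mC) or 5-hydroxymethylcytosine (5hmC). The synthesized strand therefore carried the modified base at every C, while the printed strand kept unmodified cytosine, so that modified DNA was hemi-modified. There were 18 arrays in 9 groups, 2 for each of the 3 proteins with each of the 3 kinds of DNA. The sources do not say whether the 2 arrays of a group came from separate protein preparations, so p-values measure only the spread between these arrays, which may be technical replicates.

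For each array the authors deposited a median signal and a median local background per probe, an intensity on a linear scale per the file headers, for 40330 probes with 35 variable bases. The scanner, its settings and the image software are not given in the sources used here. The authors also deposited a z-score per array for 65530 of the 65536 possible 8-mers, and how this score was made is not given in the sources used here. From the values, its median was near 0 on each array and its scale was linear, not logarithmic. Each orientation of an 8-mer had its own z-score. It ranked with the median background-subtracted signal of the probes that held the 8-mer on the synthesized strand (Spearman rho from 0.957 to 0.975 over the 18 arrays) and less with that of probes that held it on the printed strand (from -0.0804 to 0.507). An 8-mer is therefore written as it reads on the modified strand. The 8-mers were carried by a median of 17 probes each (13 to 21 from the 5th to the 95th percentile, taken over the array design). Values for 409 8-mers that no probe carried were left out, 6 cells were null and stayed missing, and 65121 8-mers were tested. One null cell belonged to TGACGCAA on JUND 5mC replicate 2.

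The main fit used limma 3.58.1 in R 4.3.3 on the deposited z-scores of all 18 arrays, with one mean per group (9 residual degrees of freedom, 10.7 prior degrees of freedom), empirical Bayes moderation with a mean-variance trend, two-sided tests and Benjamini-Hochberg adjustment over all tested 8-mers at 0.05. Each 8-mer thus had 1 spread shared by all groups. An 8-mer that varied widely on the arrays of 1 protein was therefore harder to call for the other proteins too. In turn, where the arrays of a group varied more than those of other groups, the shared spread was too small for it. Its p-values can then be too low. For each protein, 5mC was compared with C, 5hmC with C, and 5hmC with 5mC, and the 6 differences of effects between proteins were tested as interaction contrasts. Lists of 8-mers were tested with limma's camera, which compares a list with all other 8-mers, with a preset correlation of 0.01 and again with the correlation estimated, and adjusted over 144 tests. A count of changed members of a list is given over all tested 8-mers and, in the words adjusted over the list alone, with the adjustment made within the list. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and matplotlib 3.10.9 drew the plots.

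The 16 lists took 8-mers by sequence on either strand. They were the cAMP response element (CRE) core, the CRE half-site TGACGT outside that core, the PAR bZIP site, the AP-1 site, the CRE-C/EBP chimera (TGAC joined to GCAA with a CpG between them), the C/EBP palindrome, the CpG-free composite (core TGATGCAA), CGCAA outside these lists, GCAA after a base other than C, and TGAC in 8-mers without CpG. Control lists were the E-box, the GC box, the ETS, GATA and homeodomain sites, and 8-mers of A and T alone. The 8-mers named were 12 key 8-mers, for each comparison with C up to 5 with the largest rise and 5 with the largest fall that passed the test with no overlap between the arrays, and the 5 with the highest mean z-score of each group. An 8-mer was called bound on an array at a z-score of 4 or more, with 3 and 6 as alternatives. For each tetranucleotide, reverse complements merged, the mean change of the 8-mers that held it was ranked.

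To compare the strands, log2 signals of the probes holding an 8-mer in each orientation were summarised by their median per array, centred on the array median and tested in limma for 49 named 8-mers that are not palindromes, in 294 tests adjusted together. These comparisons, the tests, the lists, the key 8-mers, the naming rule and the alternatives listed next were fixed before the data were examined.

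The alternatives were a fit with the replicate number as a block, moderation without a trend, a fit of only the 6 arrays of a protein, and quantile normalization between arrays. They also took in rescaling of each array by its robust standard deviation, 8-mers with a z-score of 2 or more, z-scores recomputed from log2 probe signals with and without normexp background correction (offset 50) and with orientations merged, and leaving out each array in turn, where the lone array left is assumed to vary like the other groups. In that last alternative only the comparisons that use the array left out were refitted. After the data were seen, recomputed z-scores with the orientations apart, 8-mers with 10 or more probes, an inverse hyperbolic sine scale, a fit without JUND 5hmC replicate 2, crossed replicate numbers and a split of lists and tetranucleotides by strand, and counts of 8-mers with GCAA on 1 strand alone, were added. The files give no slide or scan date, so no batch could be tested. The steps were tested on simulated data with the spread of these arrays over 65115 8-mers. For CREB1 with 5mC, 88 percent of the 8-mers changed by 5 z-score units and 94 percent of those changed by 10 were recovered. The simulated noise was independent, with 1 spread per 8-mer in all groups, and the changes were planted at 8-mers taken at random. These shares therefore do not describe recovery at bound sites, where the spread differed between groups.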

Results

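The data were fluorescence readings of CREB1, ATF1 and JUND on arrays whose probes together hold nearly every 8-base sequence, with 2 arrays for each protein on unmodified, 5mC and 5hmC DNA. CREB1 and ATF1 are closely related bZIP proteins that bind the cAMP response element (CRE, TGACGTCA), and JUND is a bZIP protein of the AP-1 family, which binds TGACTCA. The series title names the question, whether 5mC and 5hmC increase binding of CREB1 to GCAA, the half-site of the C/EBP proteins. Values are deposited z-scores given as mean ± SD (n = 2 arrays per group), and p-values are limma's, adjusted by Benjamini-Hochberg. Arrays differed in brightness: the median probe signal ran from 519 on JUND 5hmC replicate 2 to 8014 on JUND 5mC replicate 1, and signal over background from 1.55 to 14.0 on the same arrays. Between 0 and 84 probes per array were saturated, and the small number of arrays limits the precision of every value. The z-scores of the 2 arrays of a group correlated across 8-mers, which are not independent replicates, with Pearson r of 0.955 for CREB1 and 0.951 for ATF1 on unmodified DNA, 0.649 for JUND on unmodified DNA and 0.288 for JUND with 5hmC.

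On unmodified DNA CREB1 and ATF1 had their highest z-scores at sites with the ACGT of the CRE, and JUND at other sequences. CREB1 had its highest mean z-score at TGACGTCA, the full CRE palindrome (165 ± 39.97), followed by ACGTCACA (159 ± 26.9), TGACGTAA (150 ± 5.69), GACGTCAC (150 ± 26.9) and ATGACGTA (135 ± 0.758). ATF1 had the highest values at TACGTCAC (108 ± 18.8), ACGTCACA (108 ± 21.8), TGACGTCA (106 ± 22.4), GTGACGTA (104 ± 14.2) and ATGACGTA (102 ± 10.0). Of the 19 probes with TGACGTCA, 11 and 12 were saturated on the unmodified ATF1 arrays and 4 and 8 on those of CREB1, so the TGACGTCA value of ATF1 is a lower bound and its rank is not known. Saturation was counted by site only for the 12 key 8-mers. For JUND the highest z-scores lay at C-rich 8-mers that a single probe carried, such as CCCCCGGC (187 ± 135) and AGTCCCCC (125 ± 65.7), while AP-1 sites were lower, such as TGAGTCAT (70.4 ± 50.8, 18 probes) and TGACTCAT (58.5 ± 56.7, 14 probes). The 2 unmodified JUND arrays differed widely, with 98.6 on replicate 1 and 18.4 on replicate 2 at TGACTCAT. The number of 8-mers bound at a z-score of 4 or more was 3334 ± 803 for CREB1, 1940 ± 18.4 for ATF1 and 640 ± 560 for JUND.

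**Figure D1:**
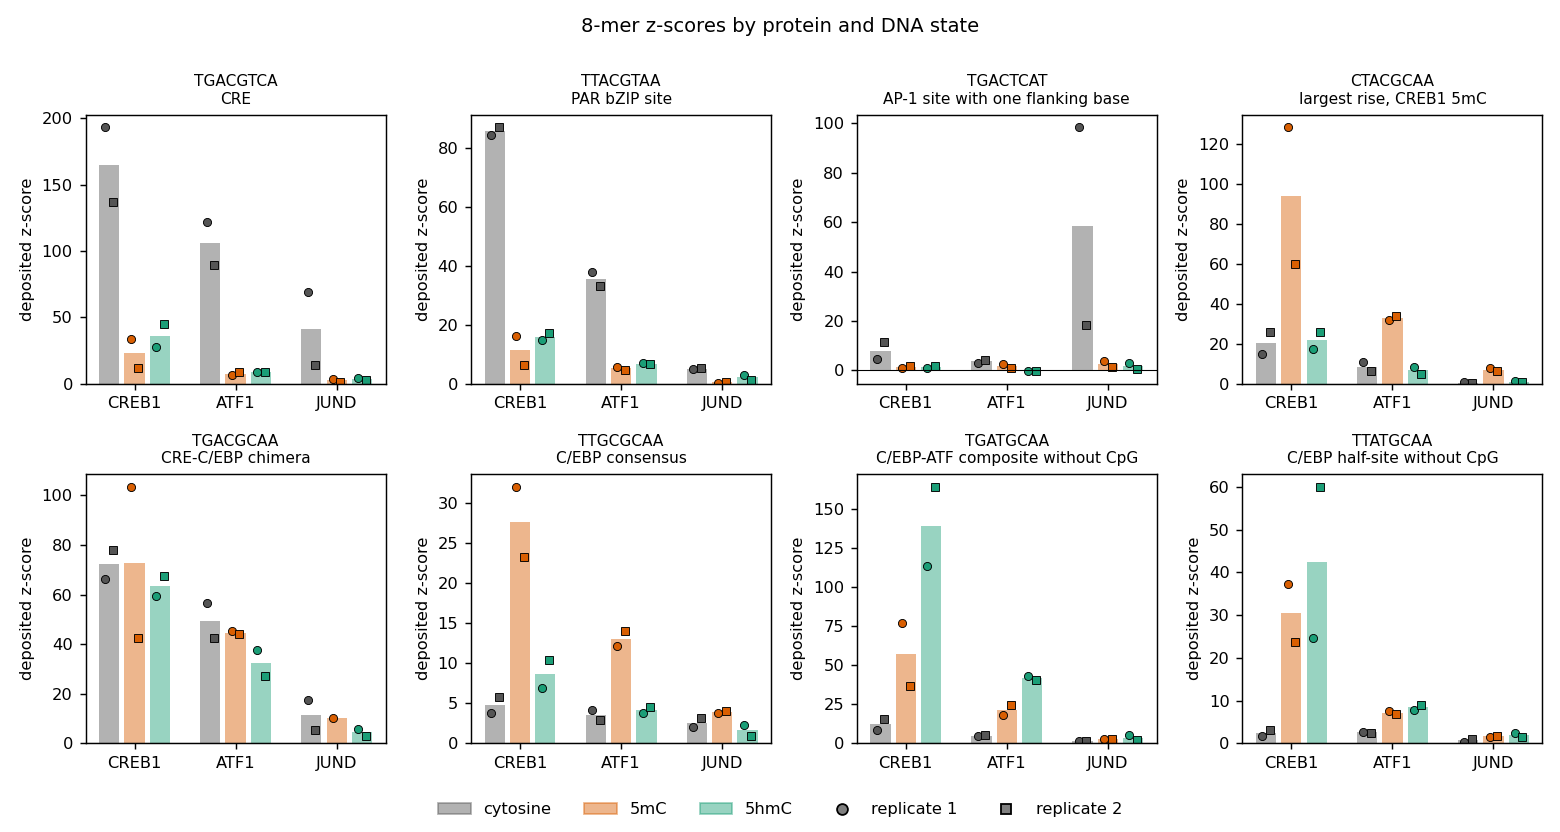
Deposited z-scores (vertical axes) of 8 named 8-mers for CREB1, ATF1 and JUND on unmodified, 5mC and 5hmC DNA, where bars are group means starting at 0 and points are the single arrays. For CREB1 the TGACGTCA mean was 165 without modification, 22.8 with 5mC and 36.2 with 5hmC, while TGATGCAA went from 12.1 to 56.8 with 5mC, which did not pass the test, and to 139 with 5hmC.

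With 5mC, CREB1 lost most of its binding to CRE sites and gained z-score at some sites with GCAA, the C/EBP half-site. The CRE palindrome TGACGTCA fell from 165 ± 39.97 on unmodified DNA to 22.8 ± 15.3 with 5mC (adjusted p = 1.91e-06). The C/EBP palindrome TTGCGCAA rose from 4.77 ± 1.475 to 27.7 ± 6.15 (adjusted p = 1.97e-05). CTACGCAA, which holds GCAA after a C, rose from 20.3 ± 7.95 to 94.3 ± 48.4 (adjusted p = 0.0051) and had the highest mean z-score of CREB1 on 5mC DNA. The call at TTGCGCAA was lost in 2 of 19 alternatives (adjusted p = 0.0514 with only the CREB1 arrays and 0.0683 with normexp and orientations apart), and that at CTACGCAA in 3 of the log2 recomputations (0.389 to 0.874). In all, 5503 of 65121 8-mers changed, 1462 higher and 4041 lower, and 12103 had an unadjusted p under 0.05.

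Sites with the central ACGT of the CRE fell as a class on 5mC DNA. All 15 members of the CRE core list fell, from a mean z-score of 79.7 ± 1.39 to 6.68 ± 2.93. All 80 members of the CRE half-site list also fell, from 72.2 ± 4.91 to 5.80 ± 1.68 (camera adjusted p = 4.04e-35 for the core and 1.12e-112 for the half-site, and 0.00959 for each with an estimated correlation). The counts were the same adjusted over the list alone. The largest falls were at ACGTCACA (159 ± 26.9 to 5.07 ± 4.56, adjusted p = 5.62e-07), TGACGTCA, GACGTCAC (150 ± 26.9 to 11.4 ± 7.67, adjusted p = 3.19e-06), TACGTCAC (130 ± 2.01 to 4.26 ± 1.35) and CACGTCAT (128 ± 18.9 to 5.49 ± 1.30). TGACGTAA fell from 150 ± 5.69 to 33.4 ± 22.1, TGACGTGG from 123 ± 9.02 to 8.92 ± 1.52 and ATGACGTC from 110 ± 1.76 to 11.4 ± 0.964. The PAR site TTACGTAA, bound by the proline- and acid-rich bZIP proteins, fell from 85.6 ± 1.82 to 11.3 ± 6.99 (adjusted p = 5.01e-05). All 15 members of its list fell (list mean 52.3 ± 11.7 to 6.83 ± 3.67, adjusted p = 0.0703 with an estimated correlation). Of 1283 8-mers with TGAC and no CpG, 359 fell and 2 rose, or 515 and 6 adjusted over the list alone, and their mean went from 2.90 to 0.658 (adjusted p = 0.137 with an estimated correlation). Among the controls, 29 of 48 E-box 8-mers, the bHLH site CACGTG that shares ACGT with the CRE, fell, or 31 adjusted over the list alone (8.69 ± 1.81 to 2.26, adjusted p = 0.188 with an estimated correlation). CCACGTGG, an E-box, fell from 7.56 ± 4.15 to 1.09 ± 0.494 (adjusted p = 0.0011). The fall at TGACGTCA kept its call in 15 of 19 alternatives and lost it in the 4 with z-scores recomputed on a log2 scale, where the adjusted p ran from 0.0816 to 0.374. The call at TGACGTAA was lost in the 2 of these with orientations apart (0.386 and 0.509), and those at TTACGTAA and CCACGTGG with quantile normalization (0.174 and 0.119).

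Part of the 8-mers with GCAA rose with 5mC. Of the 15 members of the C/EBP palindrome list, 12 rose, or 13 adjusted over the list alone (mean 2.14 ± 0.671 to 13.8 ± 4.37, camera adjusted p = 7.34e-22, and 0.015 with an estimated correlation). Of 480 other 8-mers with CGCAA, 228 rose and 37 fell, or 252 and 44 adjusted over the list alone (mean 1.77 to 7.89, camera adjusted p = 2.31e-35, adjusted p = 0.0637 with an estimated correlation). Of 1471 8-mers with GCAA after another base, 362 rose and 9 fell, or 531 and 18 adjusted over the list alone (mean 0.0666 to 1.92, camera adjusted p = 1.14e-28, adjusted p = 0.051 with an estimated correlation). After CTACGCAA, the largest rises were at ACGCAATA (15.2 ± 5.34 to 87.9 ± 53.6, adjusted p = 0.013) and CGCAATAC (7.07 ± 2.03 to 71.9 ± 39.2, adjusted p = 0.0016). They were followed by CACGCAAT (10.3 ± 3.74 to 74.3 ± 35.5, adjusted p = 0.00348) and TACGCAAT (24.1 ± 8.25 to 80.4 ± 38.5, adjusted p = 0.0426). The call at TACGCAAT was kept in 9 of 19 alternatives and lost with the replicate number as a block (adjusted p = 0.0511), and its change was negative in the log2 recomputations with orientations merged (-1.96, and -1.79 with normexp), as was that of ACGCAATA with normexp (-0.455). The calls at CGCAATAC (0.126 and 0.0657) and CACGCAAT (0.397 and 0.225) were lost in the 2 recomputations with normexp, and with only the CREB1 arrays in the fit those at CGCAATAC (0.0838) and TTATGCAA (0.441) were lost. The CpG-free TTATGCAA rose from 2.41 ± 1.03 to 30.5 ± 9.55 (adjusted p = 0.0182), a call also lost in 3 of the log2 recomputations (0.0965 to 0.227), whereas TGATGCAA was at 12.1 ± 4.69 and 56.8 ± 28.3 and did not pass the test (adjusted p = 0.112). The CRE-C/EBP chimera list was mixed, with 6 of 30 members higher and 19 lower, or 7 and 20 adjusted over the list alone (mean 30.6 to 15.5, camera adjusted p = 2.64e-08, adjusted p = 0.318 with an estimated correlation). TGACGCAA itself was at 72.2 ± 8.28 and 72.9 ± 43.1 (adjusted p = 0.989). By array it read 66.4 and 78.1 without modification and 103 and 42.4 with 5mC. Before scaling, its signal above the array median was 14826 and 22037.5 without modification and 26177 and 40557 with 5mC. As a fold of the array median it was 18.7 and 15.3, and 32.7 and 11.1. Its equal mean z-scores therefore do not show that 5mC left this site unchanged. Of the CpG-free composite list, 7 of 30 rose and 4 fell, or 12 and 6 adjusted over the list alone (mean 2.75 to 7.12, camera adjusted p = 0.0164, adjusted p = 0.746 with an estimated correlation).

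None of the 94 GC box and 95 ETS 8-mers changed with 5mC in the limma fit, 1 of 96 GATA 8-mers rose and 1 fell, 4 of 48 homeodomain 8-mers fell, and 1 of 254 8-mers of A and T alone fell. The camera adjusted p of these lists were 0.918, 0.727, 0.85, 0.114 and 0.727. For the GC box list the mean change was negative (-0.25) while the set test pointed up. The 16 AP-1 8-mers, with means of 4.90 and 1.74, had no member that passed the test (camera adjusted p = 0.779). The number of changed 8-mers was 3195 without CREB1 C replicate 2. Quantile normalization gave 2037, of which 57.3 percent were lower, against 73.4 percent in the main fit. The calls at TTATGCAA, ACGCAATA and TACGCAAT were lost without CREB1 C replicate 1 (adjusted p = 0.0742, 0.0895 and 0.27), without CREB1 C replicate 2 (0.0825, 0.0875 and 0.192) or without CREB1 5mC replicate 1 (0.168, 0.117 and 0.401), that of the CpG-free composite list without CREB1 C replicate 1 (0.343) or CREB1 5mC replicate 1 (0.426).

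**Figure D2:**
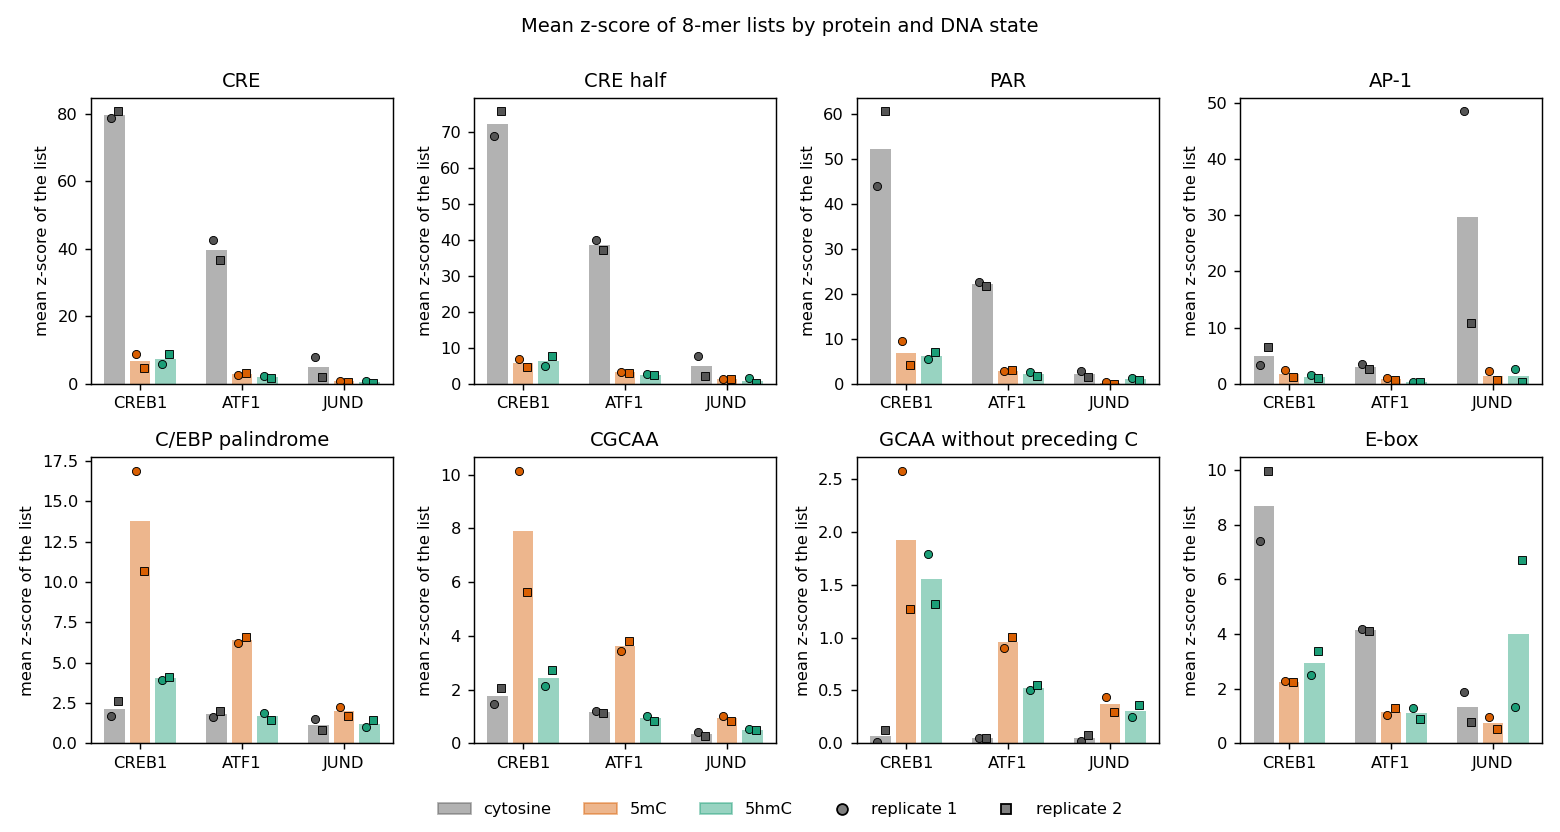
Mean z-score (vertical axes) of the 8-mers of 8 lists on each array of CREB1, ATF1 and JUND, by kind of DNA, with each point 1 array. For CREB1 the CRE half-site list mean was 72.2 on unmodified DNA and 5.80 with 5mC, and the C/EBP palindrome list mean was 2.14 and 13.8.

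With 5hmC, the z-scores of CREB1 also fell at CRE sites, and its 5 largest rises were at 8-mers with TGCA and no CpG. TGACGTCA fell from 165 ± 39.97 to 36.2 ± 12.3 (adjusted p = 6.14e-06). TGATGCAA, a composite of TGA and GCAA without a CpG, rose from 12.1 ± 4.69 to 139 ± 35.7 (adjusted p = 1.91e-05) and had the highest mean z-score of CREB1 on 5hmC DNA. In all, 5140 8-mers changed, 728 higher and 4412 lower, and 12144 had an unadjusted p under 0.05.

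All 15 members of the CRE core list and all 80 of the CRE half-site list fell with 5hmC, to means of 7.34 and 6.31 (adjusted p = 0.00959 for each with an estimated correlation), and adjusted over the list alone the counts were the same. ACGTCACA fell to 4.01 ± 1.31 (adjusted p = 4.65e-07), GACGTCAC to 6.38 ± 2.71, TACGTCAC to 2.25 ± 0.568, CACGTCAT to 1.62 ± 1.10 and TGACGTAA to 47.1 ± 12.7 (adjusted p = 1.9e-07). TGACGTGG fell to 15.3 ± 4.396 and ATGACGTC to 12.8 ± 9.06. The 15 PAR 8-mers all fell (mean 6.27, adjusted p = 0.0703 with an estimated correlation), with TTACGTAA at 16.0 ± 1.70 (adjusted p = 0.000111). In the TGAC list without CpG, 316 fell and none rose, or 435 and 2 adjusted over the list alone (adjusted p = 0.188 with an estimated correlation). The chimera list had 19 of 30 members lower and none higher, or 21 lower adjusted over the list alone (mean 9.42, camera adjusted p = 9.37e-17, adjusted p = 0.137 with an estimated correlation). TGACGCAA was at 63.4 ± 5.88 (adjusted p = 0.793). Of the E-box 8-mers 27 fell, or 32 adjusted over the list alone (mean 2.94, adjusted p = 0.21 with an estimated correlation). CCACGTGG fell to 2.53 ± 0.746 (adjusted p = 0.0106).

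After TGATGCAA, the largest rises of CREB1 with 5hmC were at TTATGCAA (2.41 ± 1.03 to 42.3 ± 25.0, adjusted p = 0.00101) and GATGCAAT (1.78 ± 1.19 to 39.7 ± 14.1, adjusted p = 0.00101). Next were GTGATGCA (5.31 ± 2.89 to 35.8 ± 6.57, adjusted p = 3.93e-05) and TATGCAAC (1.57 ± 1.15 to 27.0 ± 17.2, adjusted p = 0.0021). The rise at TGATGCAA kept its call in all 18 alternatives. The other 4 lost theirs with only the CREB1 arrays in the fit (adjusted p = 0.241, 0.195, 0.163 and 0.157), and GATGCAAT and GTGATGCA also with orientations merged on the log2 scale (0.689 and 0.411) and with normexp (0.124 and 0.291). Of 30 CpG-free composite 8-mers 10 rose and 6 fell, or 15 and 7 adjusted over the list alone (mean 2.75 to 11.1, camera adjusted p = 0.00589, adjusted p = 0.689 with an estimated correlation). Of 1471 8-mers with GCAA after a base other than C, 212 rose and 12 fell, or 283 and 19 adjusted over the list alone (mean 1.55, camera adjusted p = 4.2e-20, adjusted p = 0.107 with an estimated correlation). Most of the 728 8-mers that rose were outside these lists. By contrast, 3 of the 480 CGCAA 8-mers rose and 34 fell (mean 2.42, camera adjusted p = 0.221). That list joins both strands. Over all 8-mers with CGCAA, 1 rose and 0 fell on the modified strand (mean change 2.43). On the unmodified strand 2 rose and 41 fell (mean change -1.33). No member of the C/EBP palindrome list passed the test (mean 4.02, camera adjusted p = 0.0432, adjusted p = 0.615 with an estimated correlation). TTGCGCAA was at 8.70 ± 2.45 (adjusted p = 0.55). The set tests of A/T-only, homeodomain and GATA 8-mers were positive (camera adjusted p = 1.47e-10, 0.000182 and 0.0198, adjusted p = 0.575, 0.591 and 0.591 with an estimated correlation), with 2, 1 and 0 members higher and 0, 2 and 2 lower. TTAATTAA, an A/T-only control, was at -0.336 ± 0.274 and 1.24 ± 1.67 (adjusted p = 0.134).

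The number of 8-mers changed by 5hmC for CREB1 was 2812 without CREB1 C replicate 2 and 2869 without CREB1 5hmC replicate 1. The list calls of the CpG-free composite were lost without CREB1 C replicate 1 (adjusted p = 0.163) or 5hmC replicate 2 (0.0594), those of the C/EBP palindrome without the same arrays (0.14 and 0.102), and those of GATA without 5hmC replicate 1 (0.083) or C replicate 2 (0.17), as was the call at CCACGTGG without the latter arrays (0.132 and 0.268). The call at TGACGTCA was lost in the 4 log2 recomputations (0.712 to 0.93), and that at TGACGTAA in 5 of 18 alternatives (at most 0.951, where its change was 0.707). With normexp the calls at TTACGTAA (0.344 merged, 0.474 apart), and with orientations apart those at TGACGTGG (0.305) and ATGACGTC (0.274), were lost, and with quantile normalization those at TTACGTAA (0.605), ATGACGTC (0.0659) and CCACGTGG (0.683).

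The direct comparison of the modifications asked whether 5hmC and 5mC had the same effect on CREB1, and sites with GCAA after C were lower with 5hmC. C/EBP palindrome 8-mers were lower with 5hmC than with 5mC (9 of 15 fell, or 13 adjusted over the list alone; camera adjusted p = 6.76e-26, and 0.00959 with an estimated correlation). The same held for CGCAA, where 178 of 480 fell and 1 rose, or 250 and 4 adjusted over the list alone (camera adjusted p = 2.61e-55, and 0.021 with an estimated correlation). TTGCGCAA was at 27.7 ± 6.15 with 5mC and 8.70 ± 2.45 with 5hmC (adjusted p = 0.00221), and CTACGCAA at 94.3 ± 48.4 and 21.9 ± 6.05 (adjusted p = 0.0384). TGATGCAA was higher with 5hmC (139 ± 35.7 against 56.8 ± 28.3, adjusted p = 0.0159), as was GTGATGCA (35.8 ± 6.57 against 16.6 ± 4.81, adjusted p = 0.0291). In the CpG-free composite list 2 rose and none fell, with a mean change of 3.94 and a median of -0.18. TGACGTCA did not differ by the test (adjusted p = 0.786), and no member of the CRE core or half-site lists passed it. In all, 620 8-mers differed, 121 higher and 499 lower with 5hmC, with 8000 at an unadjusted p under 0.05. Of the 620, 366 had a mean z-score of 4 or more in any kind of DNA. Most of the 620 were outside the C/EBP palindrome and CGCAA lists. This number was 200 without CREB1 5hmC replicate 1 and 250 without CREB1 5hmC replicate 2, and 289 with only the CREB1 arrays in the fit.

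CRE sites of ATF1 fell with 5mC in the same direction as CREB1, and 8-mers with GCAA were among its gains. TGACGTCA fell from 106 ± 22.4, a lower bound because most of its probes were saturated, to 7.64 ± 1.35 (adjusted p = 0.00266), and TGACGTAA from 98.4 ± 6.48 to 12.1 ± 0.151 (adjusted p = 0.000107). CCCGCAAT rose from 1.05 ± 0.959 to 23.8 ± 3.51 (adjusted p = 0.0195) and TCCGCAAT from 1.06 ± 0.563 to 13.2 ± 2.06 (adjusted p = 0.0367). In all, 2118 8-mers changed, 777 higher and 1341 lower, with 11275 at an unadjusted p under 0.05. Of the 2118, 847 had a mean z-score of 4 or more in any kind of DNA, 187 higher and 660 lower.

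Of the 15 CRE core 8-mers 12 fell for ATF1 with 5mC, and 15 adjusted over the list alone (mean 39.6 ± 4.09 to 2.89, camera adjusted p = 7.53e-20, and 0.021 with an estimated correlation). Of the 80 CRE half-site 8-mers 65 fell, and 80 adjusted over the list alone (mean 38.5 to 3.12, camera adjusted p = 5.05e-64, and 0.0273 with an estimated correlation). The other large falls were at TACGTCAC (108 ± 18.8 to 2.65 ± 0.616, adjusted p = 0.0012), ACGTCACA (108 ± 21.8 to 3.38 ± 0.639), GTGACGTA (104 ± 14.2 to 7.01 ± 1.02) and ATGACGTA (102 ± 10.0 to 8.54 ± 3.77). TGACGTGG fell from 60.7 ± 3.10 to 5.50 ± 0.291 (adjusted p = 0.0358) and ATGACGTC from 59.4 ± 7.80 to 5.55 ± 1.27 (adjusted p = 0.0347). Of the PAR 8-mers 7 fell, or 15 adjusted over the list alone (mean 22.1 to 2.94, adjusted p = 0.23 with an estimated correlation). TTACGTAA at 35.5 ± 3.31 and 5.17 ± 0.698 did not pass the test (adjusted p = 0.123). In the C/EBP palindrome list 3 of 15 rose, or 7 adjusted over the list alone (mean 1.79 to 6.39, camera adjusted p = 1.5e-07, adjusted p = 0.137 with an estimated correlation). In the CGCAA list 83 of 480 rose and 18 fell, or 157 and 41 adjusted over the list alone (mean 1.16 to 3.63, camera adjusted p = 2.24e-12, adjusted p = 0.29 with an estimated correlation). TTGCGCAA was at 3.56 ± 0.935 and 13.1 ± 1.39 (adjusted p = 0.0879) and CTACGCAA at 8.48 ± 3.24 and 32.9 ± 1.31 (adjusted p = 0.495). The spread in these tests is shared with CREB1, whose SD at CTACGCAA with 5mC was 48.4. A value that did not pass here therefore does not show that ATF1 had no rise. TGACGCAA, the chimera, was at 49.4 ± 9.87 and 44.5 ± 0.813 (adjusted p = 0.899) and had the highest mean z-score of ATF1 on 5mC DNA. Before scaling, its signal above the array median was 23919.5 and 17619.5 without modification and 38544 and 33700.5 with 5mC. As a fold of the array median it was 14.5 and 8.70, and 11.8 and 10.2. The CpG-free composite list had no member higher and 3 lower, with a mean that went from 1.95 to 3.40 while the set test pointed down (camera adjusted p = 0.912). The other 3 of the 5 largest rises that passed the test, GGTACCCC, GTACCCCG and TACCCCGC, shared 1 probe (-1.79 ± 0.313 to 9.71 ± 1.72, adjusted p = 0.0407). The change of GGTACCCC was near 0 in the log2 recomputation with orientations merged (-0.0177). These 3 kept their call in 9 of 17 alternatives.

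The ATF1 count with 5mC depended on every array: it was 39 without 5mC replicate 2, 171 without 5mC replicate 1, 291 without C replicate 2 and 294 without C replicate 1, and 5124 with only the ATF1 arrays in the fit. Without ATF1 C replicate 1 or 5mC replicate 2 the calls at TGACGTCA (adjusted p = 0.098 and 0.0561) and ACGTCACA (0.0819 and 0.0517) were lost, as were that at TACGTCAC without 5mC replicate 2 (0.0517) and those at GTGACGTA and ATGACGTA without C replicate 1 (0.0845 and 0.0592), and those at TGACGTGG, ATGACGTC and the 5 rises were lost without any 1 of the 4 arrays (at most 0.278, 0.286 and 0.286). The call at TGACGTCA was also lost in the 4 log2 recomputations (0.0757 to 0.245) and that at TGACGTAA in the 2 with orientations apart (0.214 and 0.44).

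With 5hmC, the same class of CRE sites fell for ATF1 and few 8-mers passed the test as higher. TGACGTCA fell from the same saturated starting value to 8.86 ± 0.126 (adjusted p = 0.00277) and TGACGTAA to 13.7 ± 2.93 (adjusted p = 0.000112). Of the CRE core list 13 of 15 fell, or 15 adjusted over the list alone (mean 1.96, camera adjusted p = 1.53e-22, and 0.0188 with an estimated correlation). Of the CRE half-site list 66 of 80 fell, or 80 adjusted over the list alone (mean 2.56, camera adjusted p = 6.13e-73, and 0.021 with an estimated correlation). In all, 1418 8-mers changed, 65 higher and 1353 lower, with 9179 at an unadjusted p under 0.05. None of the 721 changed 8-mers that were bound in any state was higher. With quantile normalization, 353 8-mers were called higher and 1381 lower.

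ACGTCACA fell to 0.779 ± 0.839 and TACGTCAC to 1.53 ± 0.268 (adjusted p = 0.000899), GTGACGTA to 7.74 ± 0.508 and ATGACGTA to 9.99 ± 0.126. TGACGTGG fell to 5.19 ± 1.04 (adjusted p = 0.0406) and ATGACGTC to 5.18 ± 0.761 (adjusted p = 0.0394), calls that were lost with the replicate number as a block (0.052 and 0.0509). The largest rises among the 8-mers that passed the test ended at low z-scores. TGCAATTA went from -0.282 ± 0.215 to 3.97 ± 0.286 (adjusted p = 0.0355) and TGCAATTT from -0.671 ± 0.177 to 2.87 ± 0.301 (adjusted p = 0.0134). ACTTAATA went from 0.0985 ± 0.635 to 3.28 ± 1.03 (adjusted p = 0.0201), and ACCCCTAA and CCCCTAAG, on 1 probe, from -2.12 ± 1.70 to 1.08 ± 0.0734. These rises kept their call in 12, 13, 10, 10 and 10 of 16 to 18 alternatives. TGATGCAA was at 4.80 ± 0.269 without modification and 41.7 ± 1.67 with 5hmC, above both unmodified arrays on both arrays, but did not pass the test (adjusted p = 0.304). The main fit shares its spread with CREB1, whose SD at TGATGCAA with 5hmC was 35.7. TGATGCAA did pass with only the ATF1 arrays in the fit (adjusted p = 1.53e-05). In the CpG-free composite list 6 of 30 fell, or 7 fell and 3 rose adjusted over the list alone (mean 1.95 to 3.98), and the set test pointed down (camera adjusted p = 0.741). No C/EBP palindrome 8-mer passed the test (camera adjusted p = 0.912), and 19 of the 480 CGCAA 8-mers fell (camera adjusted p = 0.37). Over all 8-mers with CGCAA, 0 fell on the modified strand (mean change 0.295) and 24 on the unmodified strand (-1.03). Compared with 5mC directly, 472 8-mers differed, 87 higher and 385 lower (10633 at an unadjusted p under 0.05). Of the 472, 100 had a mean z-score of 4 or more in any kind of DNA, all lower with 5hmC. Of the 480 CGCAA 8-mers 40 were lower with 5hmC and none higher (mean 3.63 with 5mC and 0.925 with 5hmC, adjusted p = 0.191 with an estimated correlation). Of the C/EBP palindrome 8-mers 3 of 15 were lower, or 6 adjusted over the list alone (adjusted p = 0.121 with an estimated correlation). Of the A/T-only 8-mers 7 were higher, or 50 adjusted over the list alone (adjusted p = 0.298 with an estimated correlation).

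The number of 8-mers changed by 5hmC for ATF1 was 86 without 5hmC replicate 1, 220 without 5hmC replicate 2, 312 without C replicate 1 and 361 without C replicate 2. The number that differed between 5hmC and 5mC was 2 without 5mC replicate 2, 22 without 5hmC replicate 2, 81 without 5mC replicate 1 and 178 without 5hmC replicate 1. Without ATF1 C replicate 1 the calls at TGACGTCA, ACGTCACA, GTGACGTA and ATGACGTA were lost (adjusted p = 0.112, 0.077, 0.0923 and 0.0677), those at TGACGTGG, ATGACGTC, TGCAATTA, TGCAATTT and ACTTAATA were lost without any 1 of the 4 arrays (at most 0.325, 0.31, 0.25, 0.132 and 0.234), those at ACCCCTAA and CCCCTAAG without C replicate 1 (0.428), 5hmC replicate 1 (0.162) or 5hmC replicate 2 (0.143). Quantile normalization moved the share of lower 8-mers with 5hmC from 95.4 to 79.6 percent and that of 5hmC against 5mC from 81.6 to 60.8 percent. The 5hmC call at TGACGTCA was lost in the 4 log2 recomputations (0.23 to 0.59), and that at TGACGTAA in the 2 with orientations apart (0.419 and 0.849) and with quantile normalization (0.0866).

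With 5mC, the z-scores of JUND fell at AP-1 sites, the class that its family is known to bind. TGACTCAT fell from 58.5 ± 56.7 to 2.65 ± 1.61 (adjusted p = 0.0465) and TGAGTCAT, which holds the same core on the other strand, from 70.4 ± 50.8 to 4.11 ± 2.52 (adjusted p = 0.0179). Of 16 AP-1 8-mers 8 fell, and 16 adjusted over the list alone (mean 29.6 ± 26.6 to 1.46 ± 1.20, camera adjusted p = 1.58e-20, adjusted p = 0.188 with an estimated correlation). Before scaling, the AP-1 signal above the array median was 7411 and 574 on the unmodified arrays and 2509 and 704.5 with 5mC, so it overlapped between the groups. In all, 679 8-mers changed, 520 higher and 159 lower, with 10844 at an unadjusted p under 0.05. Of the 679, only 147 had a mean z-score of 4 or more in any kind of DNA, 116 higher and 31 lower.

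ATGACTCA fell from 52.2 ± 43.3 to 1.84 ± 1.34 (adjusted p = 0.0254), ATGAGTCA from 52.3 ± 39.0 to 3.89 ± 3.83 (adjusted p = 0.022) and GTGACTCA from 41.8 ± 38.0 to -0.264 ± 0.696 (adjusted p = 0.03). The CRE palindrome TGACGTCA was at 41.5 ± 39.0 and 2.44 ± 1.10 and did not pass the test (adjusted p = 0.2). No member of the CRE core, CRE half-site, PAR or chimera lists did either (camera adjusted p = 0.363, 0.0247, 0.411 and 0.00526, and with an estimated correlation adjusted p = 0.955 for the half-site list and 0.72 for the chimera list). The rises were small and lay at other sequences: AATAAACC went from 1.91 ± 0.110 to 9.21 ± 2.06 (adjusted p = 0.00329, 13 probes) and CCCAGAAT from 2.18 ± 0.466 to 9.70 ± 5.60 (adjusted p = 0.0385, 11 probes). ACCCCAGC and CCCCAGCC (adjusted p = 0.0216) and ACCCCGTA (adjusted p = 0.00665) each rested on 1 probe. All 5 changes were negative in the log2 recomputation with orientations merged (-0.114 at AATAAACC and -1.87 at CCCAGAAT), and with only the JUND arrays in the fit the calls at AATAAACC (adjusted p = 0.256), CCCAGAAT (0.326), ACCCCAGC and CCCCAGCC (0.214) and ACCCCGTA (0.116) were lost. In the CGCAA list 1 member rose and 1 fell, or none adjusted over the list alone (mean 0.345 to 0.929, camera adjusted p = 0.602). Before scaling, the mean signal of this list above the array median was 63.7 and 15.0 without modification and 1299 and 1027 with 5mC. In the list of GCAA after another base 13 rose and 1 fell, or 8 and 1 adjusted over the list alone (camera adjusted p = 0.164). Of the TGAC 8-mers without CpG 19 fell and 1 rose, or 81 and 8 adjusted over the list alone (camera adjusted p = 1.47e-10, adjusted p = 0.318 with an estimated correlation). Among the control lists, the set test of the GC box also pointed down (camera adjusted p = 0.013, adjusted p = 0.575 with an estimated correlation), with 0 of 94 members changed.

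The AP-1 calls of JUND with 5mC were lost without JUND 5mC replicate 1 (adjusted p = 0.163 at TGACTCAT, 0.0726 at TGAGTCAT, 0.0982 at ATGACTCA, 0.0726 at ATGAGTCA and 0.119 at GTGACTCA) or replicate 2 (0.176, 0.0968, 0.115, 0.114 and 0.128) and with only the JUND arrays in the fit (0.774, 0.898, 0.667, 0.748 and 0.461). The rise of CCCAGAAT was lost without JUND C replicate 1 (0.153), C replicate 2 (0.0799) or 5mC replicate 2 (0.263), that of ACCCCGTA without 5mC replicate 2 (0.0566), and that of ACCCCAGC without C replicate 1 (0.0719), C replicate 2 (0.0738) or 5mC replicate 2 (0.164). The number of changed 8-mers was 151 without JUND C replicate 1, 166 without 5mC replicate 2 and 218 without 5mC replicate 1, and it was 3 with only the JUND arrays in the fit. Quantile normalization gave 1262 with 35.7 percent lower against 23.4 percent in the main fit. The count also rose when JUND 5hmC replicate 2, an array of neither group, was left out, as given below. The CRE half-site list call was lost without C replicate 1 (0.592), 5mC replicate 1 (0.0962) or 5mC replicate 2 (0.0855), and the chimera list call without C replicate 1 (0.601) or 5mC replicate 2 (0.0645).

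With 5hmC, AP-1 sites of JUND were also low, but no 8-mer passed the test. TGACTCAT was at 58.5 ± 56.7 without modification and 1.85 ± 1.82 with 5hmC (adjusted p = 0.206), and the AP-1 list mean went from 29.6 ± 26.6 to 1.45 ± 1.57 (camera adjusted p = 2.13e-27, adjusted p = 0.121 with an estimated correlation). All 16 AP-1 8-mers fell adjusted over the list alone and 0 over all tested 8-mers. With 5hmC the AP-1 list mean was 2.56 on replicate 1 and 0.338 on replicate 2. The highest 8-mers of replicate 2 were of another kind, so its low AP-1 value may not reflect JUND. The limma fit called 0 8-mers against unmodified DNA, with 6123 at an unadjusted p under 0.05, and the recomputed log2 z-scores called 80 with orientations merged. Against 5mC it called 2023, 616 higher and 1407 lower with 5hmC (12932 at an unadjusted p under 0.05), but 3 with only the JUND arrays in the fit.

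The 2 arrays of JUND with 5hmC had different highest 8-mers, as the plot of CANNTG cores shows. E-box 8-mers had means of 1.33 ± 0.792 without modification, 0.739 with 5mC and 4.00 ± 3.80 with 5hmC, and their set test was positive (camera adjusted p = 2.71e-10, adjusted p = 0.423 with an estimated correlation), but not without JUND 5hmC replicate 2 (0.986). Against 5mC, 1 E-box 8-mer was higher with 5hmC, or 17 adjusted over the list alone (adjusted p = 0.414 with an estimated correlation), and that list call was also lost without replicate 2 (0.122). The number of 8-mers changed against unmodified DNA was 50 without JUND C replicate 1, 54 without 5hmC replicate 2, 285 without C replicate 2 and 2504 without 5hmC replicate 1, which leaves only the discordant array. Against 5mC it was 546 without 5mC replicate 2, 582 without 5mC replicate 1, 1150 without 5hmC replicate 2 and 4533 without 5hmC replicate 1.

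**Figure D3:**
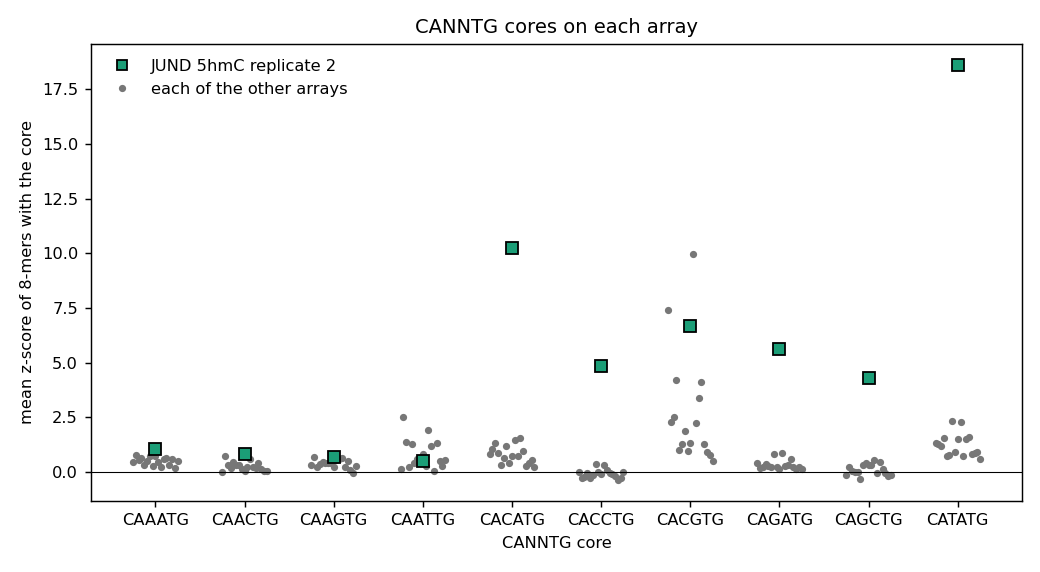
Mean z-score (vertical axis) of the 8-mers that hold each of 10 CANNTG cores (horizontal axis) on JUND 5hmC replicate 2 (squares) and on the other 17 arrays (dots). CATATG 8-mers had a mean of 18.6 on JUND 5hmC replicate 2 and 1.53 on replicate 1.

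Ranking all tetranucleotides by the mean change of the 8-mers that hold them placed GCAA first with 5mC for each protein when the replicates were averaged. For CREB1 with 5mC, GCAA was first with a mean change of 2.77, and first on each replicate number (3.92 and 1.63). TGCA was second (1.86) and ACGT last (-12.5). For ATF1 with 5mC, GCAA was first (1.26) and ACGT last (-5.86), and for JUND with 5mC, GCAA was first (0.38) and CCCC last (-1.49). By replicate number, it was first on both for ATF1, but at rank 1 on replicate 1 and rank 5 on replicate 2 for JUND. With 5hmC, GCAA was second for CREB1 (1.25, after TGCA with 1.485), at rank 4 for ATF1 (0.283) and at rank 17 for JUND (0.23). Ranked instead by the median change, GCAA stood at rank 8 for JUND and 2 for ATF1 with 5mC.

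The strand that carried the modified C mattered at GCAA sites. For TGACGCAA, read on the modified strand, the log2 probe signal of CREB1 changed by 0.21 with 5mC, and for its reverse complement TTGCGTCA it fell by 2.22, a difference of 2.42 ± 0.28 (SE, adjusted p = 8.31e-06). For TGATGCAA the effects of 5hmC were 2.42 and -0.71, a difference of 3.14 ± 0.24 (adjusted p = 2.89e-07). Those of 5mC were 1.90 and -0.55 (adjusted p = 1.8e-06). ATF1 had differences at TGATGCAA of 2.29 ± 0.24 with 5mC (adjusted p = 3.31e-06) and 2.56 ± 0.24 with 5hmC (adjusted p = 1.63e-06), and at TGACGCAA of 1.91 ± 0.28 and 1.53 ± 0.28. TTATGCAA differed by strand for CREB1 by 2.05 ± 0.32 with 5mC (adjusted p = 9.32e-05), whereas TGACGTGG, ATGACGTC and TGACTCAT did not pass the test for CREB1 (with 5mC adjusted p = 0.896, 0.199 and 0.736). For JUND no key 8-mer passed it, but 19 of the 49 8-mers did with 5mC, 13 of them higher in the named orientation, and 1 with 5hmC. Over these 8-mers and 6 comparisons, 109 of 294 tests passed, 88 with the effect higher in the named orientation and 21 lower. The key 8-mers were fixed in advance, while 8-mers named for a rise were chosen in the orientation that rose, which favours the first direction.

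**Figure D4:**
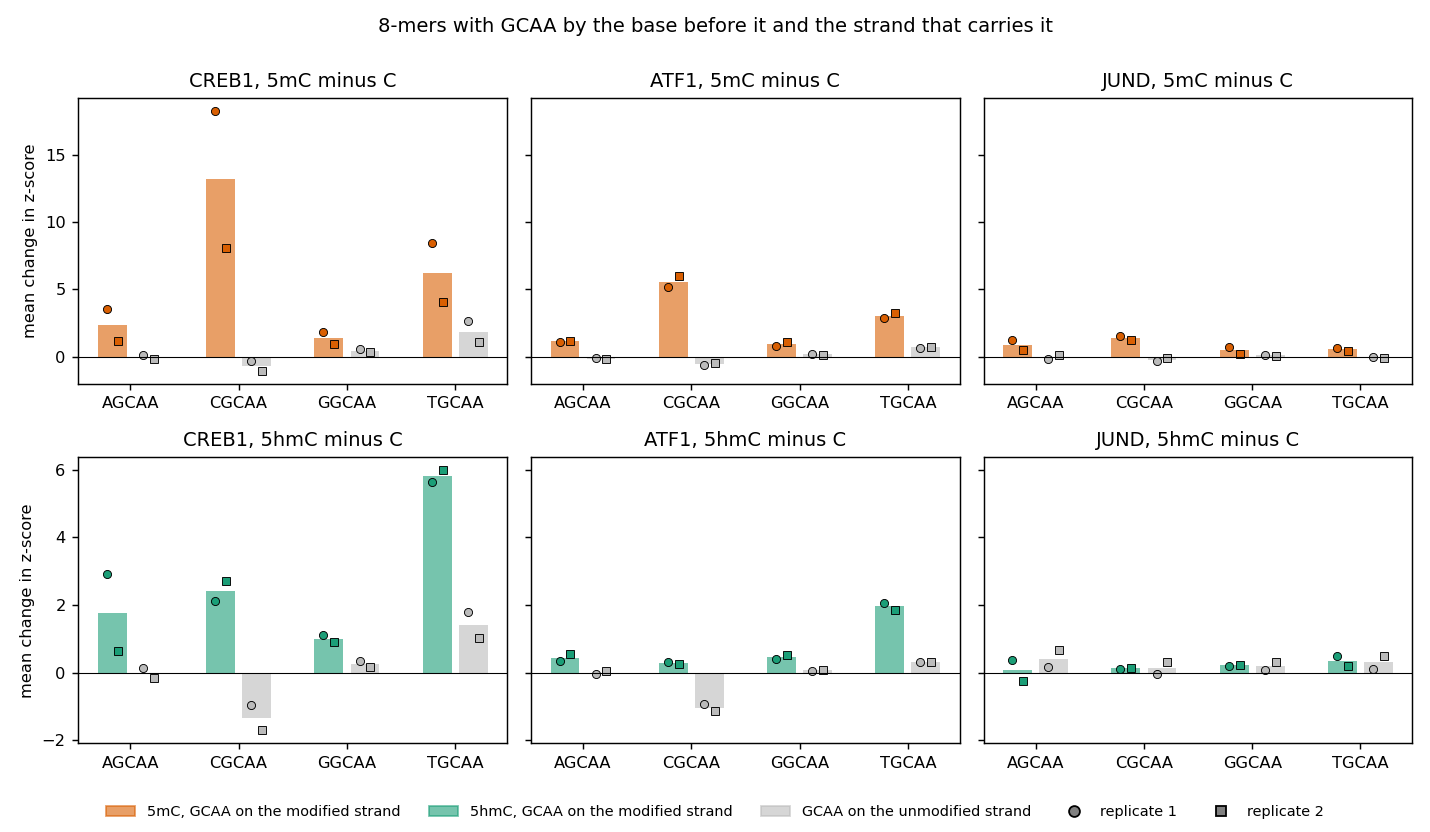
Mean change in z-score (vertical axes) with 5mC and with 5hmC over 8-mers holding AGCAA, CGCAA, GGCAA or TGCAA (horizontal axis) on the modified or the unmodified strand, for CREB1, ATF1 and JUND. For CREB1 the CGCAA mean on the modified strand was 2.38 without modification, 15.6 with 5mC and 4.80 with 5hmC, and on the unmodified strand it was 1.86 and 1.17 without and with 5mC.

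The effects of a modification on CREB1 and ATF1 correlated more closely with each other than either did with those on JUND. Across the 65121 8-mers, which overlap and are not independent replicates, the effects of CREB1 and ATF1, which share no arrays, correlated with Pearson r of 0.913 with 5mC and 0.917 with 5hmC (Spearman rho of 0.621 and 0.561). Those of CREB1 and JUND correlated with r of 0.232 and 0.274 (rho of 0.343 and 0.211), and those of ATF1 and JUND with r of 0.334 and 0.277 (rho of 0.504 and 0.161). By replicate number the 5hmC values were 0.295 and 0.0749 for CREB1 and JUND and 0.297 and 0.0392 for ATF1 and JUND, and the second of each rests on JUND 5hmC replicate 2, whose highest 8-mers were not those of its partner. These correlations were not tested against each other. Tested as a difference of effects, the fall at TGACGTAA with 5mC was larger for CREB1 than for JUND by -108 ± 12.8 (SE, adjusted p = 4.01e-05), and the rise at TTGCGCAA was larger by 21.6 ± 4.22 (adjusted p = 0.00427). Before scaling, the TTGCGCAA signal above the array median went from 334 and 190 to 5981 and 5305 for JUND. For CREB1 it went from 892 and 2043 to 8944.5 and 21388. As a fold of the array median, JUND went from 1.26 and 1.33 to 1.81 and 1.92. CREB1 went from 2.06 and 2.33 to 11.8 and 6.32. The effect of scaling on this rise was not tested. At TGACGTAA the unmodified arrays read 17.5 and 6.58 for JUND against 154 and 146 for CREB1, so JUND could hardly fall as far. On the inverse hyperbolic sine scale that difference was -0.494 (adjusted p = 0.798). With 5hmC the rise at TGATGCAA was larger for CREB1 than for JUND by 124 ± 23.1 (adjusted p = 0.00285). These 3 calls were kept in 13 of 22, 16 of 22 and 14 of 21 alternatives. That at TGACGTAA was lost without CREB1 C replicate 1 (adjusted p = 0.0715) or replicate 2 (0.104), and that at TGATGCAA without CREB1 C replicate 2 (0.0765). None of the 12 key 8-mers had an effect that differed by the test between CREB1 and ATF1, but at TGACGTCA the saturated probes on unmodified ATF1 arrays leave this open. The count of 8-mers whose 5mC effect differed between CREB1 and ATF1 was 177, but 3 without ATF1 5mC replicate 2, and for 5hmC it was 140, but 6 without ATF1 5hmC replicate 1.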

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

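The tests of difference between proteins were planned, while the tests of scaling, the inverse hyperbolic sine scale and orientations kept apart were chosen only after the result was seen. What drew attention to each of the following is a difference between groups, namely that the effect of a modification differed between proteins in a direct test. By count, the effect of 5mC differed at 177 8-mers between CREB1 and ATF1, at 2174 between CREB1 and JUND and at 9 between ATF1 and JUND, and that of 5hmC at 140, 1992 and 12.

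The CRE palindrome TGACGTCA had a change that was lower for CREB1 than for JUND by -103 z-score units with 5mC (adjusted p = 0.00737) and -90.5 with 5hmC (adjusted p = 0.0201). These calls were kept in 12 of 22 and 8 of 21 alternatives. Without CREB1 C replicate 1 the differences were -74.6 and -62.3, and without CREB1 C replicate 2 they were -131 and -119. For TGACGTAA the differences were -108 with 5mC (adjusted p = 4.01e-05) and -94.6 with 5hmC (adjusted p = 0.000141), and ATF1 differed from JUND there by -77.7 (adjusted p = 0.049) and -76.5 (adjusted p = 0.0453), calls that were lost without any 1 of 6 of the 8 arrays with 5mC (at most 0.634) and of 4 of the 8 with 5hmC (at most 0.438). The extended half-site TGACGTGG gave -109 (adjusted p = 0.00238) and -101 (adjusted p = 0.00459) for CREB1 against JUND, and ATGACGTC -93.5 (adjusted p = 0.00642) and -93.3 (adjusted p = 0.00673). The PAR site TTACGTAA gave -69.5 with 5mC (adjusted p = 0.00864) and -66.6 with 5hmC (adjusted p = 0.0125). Among sites with GCAA, the rise was larger for CREB1 than for JUND at TTGCGCAA with 5mC by 21.6 (adjusted p = 0.00427), at TGATGCAA with 5hmC by 124 (adjusted p = 0.00285) and at TTATGCAA with 5hmC by 38.6 (adjusted p = 0.0485). The call at TTATGCAA was kept in 5 of 21 alternatives and lost with the replicate number as a block (adjusted p = 0.0554). All 15 of these differences failed the test on the inverse hyperbolic sine scale (adjusted p from 0.0827 to 0.979) and with normexp and orientations apart (0.0518 to 0.991), and all but that at TTGCGCAA failed it with only the arrays of the 2 proteins in the fit. At TGACGTCA the difference was positive in all log2 recomputations with either modification, such as 7.82 with 5mC and 11.9 with 5hmC with orientations merged. A difference in z-score between proteins also depends on how strongly each bound the site without modification, and JUND had a mean of 41.5 at TGACGTCA on unmodified DNA against 165 for CREB1. At TGACGTAA the unmodified arrays read 17.5 and 6.58 for JUND against 154 and 146 for CREB1.

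A technical explanation for the falls is that a z-score is scaled by the spread of its own array, so that a brighter 5mC array could give lower z-scores for the same signal. For CRE half-sites this was tested on the background-subtracted signal above the array median. The highest such signal on a 5mC array was 24.3 percent of the lowest on an unmodified array for CREB1 and 17.7 percent for ATF1, so the falls were present before scaling and a loss of binding is the likelier explanation. For AP-1 sites of JUND the same value was 437 percent, because the unmodified JUND arrays had signals of 7411 and 574 and the 5mC arrays 2509 and 704.5. Scaling and loss of binding cannot be told apart there. For the rises, scaling was not tested. On JUND arrays, the robust standard deviation of background-subtracted 8-mer signals was 160 and 54.9 without modification and 1257 and 1262 with 5mC. The same signal above the median therefore gives a lower z-score on those 5mC arrays. A small rise of JUND in z-score with 5mC thus does not show a small gain in signal.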

How the results depend on the processing

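The tests with orientations kept apart, with 10 or more probes, on an inverse hyperbolic sine scale, without JUND 5hmC replicate 2, with crossed pairing and with tetranucleotides of the modified strand were chosen only after the result was seen, and the other alternatives were planned. Over all alternatives, 1739 results at named 8-mers and 1273 at lists kept their side of the threshold, and 20 and 4 changed sign. Another 234 and 115 became weaker, and 65 and 48 became stronger. Direction was compared only where the main or the alternative result passed the test. A change of sign between 2 results that did not pass was not counted, here or below. Rescaling each array by its robust standard deviation and recomputing linear z-scores moved no count of changed 8-mers by more than 1.5 times. The deposited z-scores already had a median near 0 on each array. Their lower quartiles ran from -0.691 to -0.560 and their upper quartiles from 0.661 to 0.881. Rescaling could therefore hardly move a count, and its result says little about other ways of scaling. With the replicate number as a block, CREB1 with 5mC had 5346 changed 8-mers against 5503, and no count moved by that much. The calls at TACGCAAT for CREB1 with 5mC (adjusted p = 0.0511) and at TGACGTGG (0.052) and ATGACGTC (0.0509) for ATF1 with 5hmC were lost. The difference between CREB1 and JUND at TTATGCAA with 5hmC also lost its call (0.0554). With crossed pairing the counts were 5349 for CREB1 with 5mC, 546 for CREB1 5hmC against 5mC and 429 for ATF1 5hmC against 5mC. The cause of the changes below was not tested. Merging orientations joins the values of an 8-mer on the modified and the unmodified strand, which differed at GCAA sites. On the log2 scale, results at named 8-mers changed sign 8 times with orientations merged and 0 times with them apart. With normexp these numbers were 7 and 1. Results that became weaker numbered 15 merged and 13 apart on the log2 scale, and 21 and 31 with normexp.

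With log2 z-scores recomputed from probe signals and orientations merged, the changed 8-mers were 2791 for CREB1 with 5mC (5503 in the planned fit), 2377 with 5hmC (5140) and 120 between the modifications (620), 1191 for ATF1 between the modifications (472), 1289 for JUND with 5mC (679) and 80 with 5hmC (0). The differences of 5mC effects were 0 for CREB1 against ATF1, 829 for CREB1 against JUND and 71 for ATF1 against JUND, and those of 5hmC effects 0, 743 and 154. Changes of sign were at TACGCAAT for CREB1 with 5mC (-1.96), at GGTACCCC (-0.0177) and TACCCCGC (-0.367) for ATF1 with 5mC, and at ACCCCAGC (-0.458), CCCCAGCC (-0.675), CCCAGAAT (-1.87), AATAAACC (-0.114) and ACCCCGTA (-1.53) for JUND with 5mC. GCAA ranked 131 between the modifications for CREB1 and 130 for ATF1, 2 for ATF1 with 5mC, 7 for ATF1 with 5hmC and 4 for JUND with 5mC. Effects correlated with r of 0.848 for CREB1 and ATF1, 0.395 for CREB1 and JUND and 0.531 for ATF1 and JUND with 5mC, and 0.850 for CREB1 and ATF1 with 5hmC.

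With normexp background correction as well, the counts were 2121 and 1881 for CREB1 with 5mC and 5hmC and 27 between them, 1242 for ATF1 with 5mC and 835 between the modifications, and 163 for JUND with 5hmC and 1176 between the modifications. The differences of effects were 0, 518 and 19 with 5mC and 0, 417 and 27 with 5hmC, in the order CREB1 against ATF1, CREB1 against JUND and ATF1 against JUND. Changes of sign were at ACGCAATA (-0.455) and TACGCAAT (-1.79) for CREB1, at GGTACCCC (-0.244) for ATF1, and at ACCCCAGC (-0.339), CCCCAGCC (-0.450), CCCAGAAT (-1.52) and ACCCCGTA (-1.41) for JUND, all with 5mC. With orientations apart and normexp, the counts were 3322 for CREB1 with 5mC and 117 between the modifications, 1264 for ATF1 between the modifications and 101 for JUND with 5hmC. The differences of effects in the same order were 0, 472 and 16 with 5mC and 0, 625 and 57 with 5hmC. TGACGTAA had a change of 0.707 for CREB1 with 5hmC. With orientations apart on the log2 scale, the counts were 3437, 2209 and 2116 for ATF1 with 5mC, with 5hmC and between them, and 2010, 36 and 5240 for JUND. The differences of effects were 0, 1278 and 81 with 5mC and 0, 1138 and 244 with 5hmC. GCAA ranked 130 for CREB1 and 129 for ATF1 between the modifications and 5 for JUND with 5mC.

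With quantile normalization, the counts were 2037 and 1831 for CREB1 with 5mC and 5hmC and 396 between them, 1418 for ATF1 between the modifications, and 1262 and 110 for JUND with 5mC and 5hmC. The differences of effects were 0, 368 and 205 with 5mC and 0, 268 and 218 with 5hmC. TGACGCAA changed sign to a rise of 56.7 for CREB1 with 5hmC, 90.5 and 46.9 for ATF1 with 5mC and 5hmC, and 24.7 for JUND with 5mC, and GCAA ranked 135 for ATF1 between the modifications. The lower share of the differences of effects between CREB1 and JUND was 59.2 percent with 5mC (84.7 in the planned fit) and 78.0 with 5hmC (94.3), and between ATF1 and JUND 64.9 percent (100) and 79.8 (91.7).

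With only the arrays of the proteins compared, the counts were 289 for CREB1 between the modifications, 5124, 3549 and 2100 for ATF1 with 5mC, with 5hmC and between them, and 3 and 3 for JUND with 5mC and between the modifications. The differences of effects were 3, 1290 and 616 with 5mC and 7, 1234 and 745 with 5hmC. With 8-mers of a z-score of 2 or more, the counts were 1441 for CREB1 between the modifications, 3511, 2782 and 1355 for ATF1, and 1339 for JUND with 5mC. Effects differed between proteins at 517, 3330 and 77 with 5mC, and with 5hmC 441 for CREB1 against ATF1 and 206 for ATF1 against JUND. GCAA then ranked 2 for ATF1 with 5hmC, 134 for ATF1 between the modifications and 40 for JUND with 5hmC, and the effects of CREB1 and ATF1 correlated with r of 0.936 with 5mC and 0.938 with 5hmC.

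On the inverse hyperbolic sine scale, the counts were 145 for CREB1 between the modifications, 2363 for ATF1 with 5hmC and 1310 between the modifications, and 1318, 140 and 3042 for JUND with 5mC, with 5hmC and between them. Between proteins, the effects differed at 1 and 241 with 5mC for CREB1 against ATF1 and against JUND, and 0, 307 and 135 with 5hmC. Without JUND 5hmC replicate 2, the counts were 1107 for ATF1 between the modifications and 1685 for JUND with 5mC. That array is in neither comparison. These counts lie outside the ranges given below, which come only from leaving out arrays of the comparison itself. Without a mean-variance trend, the differences of effects were 383 and 183 with 5mC for CREB1 against ATF1 and ATF1 against JUND, and 313 and 240 with 5hmC. With 10 or more probes, the difference of 5mC effects between ATF1 and JUND was at 17 8-mers. With an estimated correlation, 11 of the 144 list tests passed, against 76.

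Among all tetranucleotides of the modified strand, GCAA ranked 1 for CREB1 and for ATF1 with 5hmC, 255 for each between the modifications, 41 for JUND with 5hmC and 248 for JUND between the modifications. By the median change, it ranked 131 and 128 for CREB1 and ATF1 between the modifications, 2 and 11 for ATF1 with 5mC and 5hmC, 8 for JUND with 5mC and 45 for JUND between the modifications.

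Leaving out 1 array at a time gave from 3195 (CREB1 C replicate 2 left out) to 4856 (C replicate 1) changed 8-mers for CREB1 with 5mC, from 2812 to 4738 (the same arrays) with 5hmC, and from 200 (5hmC replicate 1) to 513 (5mC replicate 2) between them. For ATF1 the ranges were 39 (5mC replicate 2) to 294 (C replicate 1), 86 (5hmC replicate 1) to 361 (C replicate 2) and 2 (5mC replicate 2) to 178 (5hmC replicate 1). For JUND they were 151 (C replicate 1) to 728 (C replicate 2), 50 (C replicate 1) to 2504 (5hmC replicate 1) and 546 (5mC replicate 2) to 4533 (5hmC replicate 1). The differences of 5mC effects ranged from 3 (ATF1 5mC replicate 2) to 1327 (CREB1 C replicate 1) for CREB1 against ATF1, from 1332 (JUND 5mC replicate 2) to 2938 (CREB1 C replicate 1) for CREB1 against JUND and from 0 (JUND 5mC replicate 2) to 72 (JUND C replicate 2) for ATF1 against JUND. Those of 5hmC effects ranged from 6 (ATF1 5hmC replicate 1) to 1173 (CREB1 C replicate 1), from 1169 (CREB1 5hmC replicate 1) to 3882 (JUND 5hmC replicate 1) and from 3 (ATF1 5hmC replicate 1) to 1587 (JUND 5hmC replicate 1).

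For CREB1 5hmC against 5mC, the mean change of the CpG-free composite list ranged from 1.51 (without CREB1 5mC replicate 2) to 6.37 (without 5mC replicate 1) and that of GCAA after a base other than C from -1.02 to 0.289 (the same arrays). For JUND with 5hmC, the mean change of the GC box list ranged from -1.90 (without JUND 5hmC replicate 1) to 2.50 (without 5hmC replicate 2) and that of the A/T-only list from -0.533 to 0.952 (the same arrays).

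At the 8-mers named for CREB1 and ATF1, calls were also lost in other ways. With only the CREB1 arrays in the fit, these were TTGCGCAA (0.0514), TTATGCAA (0.441) and CGCAATAC (0.0838) with 5mC, and TTATGCAA (0.241), GATGCAAT (0.195), GTGATGCA (0.163), TATGCAAC (0.157) and CCACGTGG (0.0554) with 5hmC. With quantile normalization they were TTACGTAA (0.174) and CCACGTGG (0.119) for CREB1 with 5mC, TTACGTAA (0.605), TGACGTAA (0.0566), ATGACGTC (0.0659) and CCACGTGG (0.683) for CREB1 with 5hmC, and TGACGTAA (0.0866), TGACGTGG (0.111) and ATGACGTC (0.114) for ATF1 with 5hmC. With recomputed linear z-scores, the calls at TGACGTGG and ATGACGTC were lost for ATF1 with 5mC (0.134 and 0.106) and with 5hmC (0.172 and 0.127). Without a mean-variance trend, the 5 AP-1 calls of JUND with 5mC were lost (0.0501 to 0.109), as was that at TCCGCAAT for ATF1 with 5mC (0.0587).

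In the log2 recomputations, calls lost for CREB1 were TTATGCAA with 5mC (0.117 merged, 0.227 with normexp merged, 0.0965 with normexp apart), and with 5hmC TTACGTAA (0.344 and 0.474 with normexp), TGACGTGG (0.305), ATGACGTC (0.274) and CCACGTGG (0.254 and 0.34). For ATF1 with normexp and orientations apart they were TGACGTGG (0.0557 with 5mC, 0.233 with 5hmC), ATGACGTC (0.0728, 0.219), GTGACGTA (0.136, 0.383) and ATGACGTA (0.251, 0.659). Among rises of ATF1 they were TCCGCAAT with normexp merged (0.133), and with orientations merged TGCAATTA (0.331), TGCAATTT (0.0723), ACTTAATA (0.549), ACCCCTAA (0.46) and CCCCTAAG (0.72).

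Of the 15 differences between proteins at key 8-mers, those of CREB1 against JUND with 5mC kept their call in 12 of 22 alternatives at TGACGTCA, 16 at TTGCGCAA, 13 at TTACGTAA, 13 at TGACGTAA, 17 at TGACGTGG and 13 at ATGACGTC. With 5hmC they kept it in 8 of 21 at TGACGTCA, 14 at TGATGCAA, 13 at TTACGTAA, 11 at TGACGTAA, 15 at TGACGTGG, 13 at ATGACGTC and 5 at TTATGCAA. For ATF1 against JUND, TGACGTAA kept it in 8 of 22 with 5mC and 9 of 21 with 5hmC.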

Other observations

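In the following, the regression on base composition was written before its result, and all other tests were chosen only after the result was seen, as was the split of lists by strand. The number of GCAA sites that rose with 5mC differed by the base before GCAA and by strand, and these counts were not tested against each other. Each pentamer was held by the same number of 8-mers on the modified strand. Of those with CGCAA there, 235 rose for CREB1 with 5mC (mean change 13.2), and of those with TGCAA 205 rose (6.26), against 76 with AGCAA (2.35) and 50 with GGCAA (1.36). On the unmodified strand 12 with CGCAA rose and 44 fell, and 62 with TGCAA rose and 2 fell (32 and 2 with 5hmC), but part of the latter, such as those with TTGCAA, hold GCAA on both strands. Of the 208 8-mers with TGCAA on the modified strand and GCAA on no other, 168 rose, and of the 208 with it on the unmodified strand alone 25 rose and 2 fell (120 rose, and 6 rose and 2 fell, with 5hmC). With AGCAA and GGCAA there, 4 and 9 rose and 2 and 4 fell. With 5hmC, 1 with CGCAA, 146 with TGCAA, 32 with AGCAA and 26 with GGCAA on the modified strand rose. For ATF1 with 5mC, 84 with CGCAA and 55 with TGCAA rose, and for JUND 1 and 3. In all 4 pentamers read on the modified strand, the C of GCAA itself is modified, and in CGCAA also the C before it. The modified bases of TGCAA within the pentamer are thus the same as those of AGCAA and GGCAA.

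Over the CGCAA 8-mers outside the other lists, the mean change of CREB1 with 5mC was 12.9 on the modified strand and -0.627 on the unmodified strand. These means restate the counts above for nearly the same 8-mers and are no separate test. The chimera list was mixed on the modified strand, where 6 of 15 8-mers rose and 5 fell, and lower on the unmodified strand. It had means of 28.5 ± 3.17 and 28.2 ± 13.3 without and with 5mC on the modified strand, and 32.7 ± 2.92 and 2.72 ± 0.355 on the unmodified strand, where 14 of 15 8-mers fell. On the modified strand its change was 11.4 on replicate 1 and -12.0 on replicate 2.

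JUND 5hmC replicate 2 had a different set of highest 8-mers from its partner. Of its 100 highest 8-mers, 93 percent held CANNTG, the core of sites bound by bHLH proteins, against 0 to 2 percent on the other 17 arrays, and its highest 8-mer, ACATATGG, had a z-score of 99.4 against 1.66 on replicate 1. Noise of the dimmest array would not favour one motif, and the share was 78.2 times that among all 8-mers. An effect of 5hmC on JUND would appear on both arrays, and the mean of CATATG 8-mers on replicate 1 was 8.20 percent of that on replicate 2. Another DNA-binding protein on this array, or a mislabelled or mixed sample, is the likelier explanation, and which of these it was cannot be learned from the files.

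The changes of 8-mers without bZIP sites also correlated between proteins. Across 54087 such 8-mers, which are not independent replicates, the 5mC effects of 2 proteins correlated with Spearman rho of 0.542 for CREB1 and ATF1, 0.305 for CREB1 and JUND and 0.489 for ATF1 and JUND. With 5hmC the values were 0.488, 0.160 and 0.105, so for CREB1 and ATF1 the correlation was not particular to 5mC. For the 5mC effects, base and dinucleotide composition is not a likely cause, since 91.1 percent of the median correlation remained after regression on it. A signal of 5mC arrays that does not depend on the protein could be another cause. The lowest correlation over protein pairs and replicate numbers was 0.178. Such a signal and a shared effect on the proteins both predict a positive correlation, so this value cannot tell them apart.

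The highest z-score of 5 of the 6 JUND arrays, all but 5hmC replicate 2, and of both ATF1 arrays with 5hmC lay at a C-rich 8-mer carried by 1 probe. CCCCCGGC (1 probe) was at 187 ± 135, 15.4 ± 9.64 and 272 ± 331 for JUND on unmodified, 5mC and 5hmC DNA (adjusted p = 0.29 and 0.806 against unmodified DNA), and at 53.7 ± 2.31 for ATF1 with 5hmC.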
